A study of Mus musculus with 8 samples.

How the data were processed

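Messenger RNA was measured by sequencing in freshly isolated mouse small intestinal crypts and in freshly isolated small intestinal myofibroblasts, with 4 samples of each kind. Per the labels' protocols, a crypt sample came from 1 mouse and a myofibroblast sample was pooled from 2 mice. Crypts were released with EDTA. Myofibroblasts were obtained from the tissue left after EDTA washes by collagenase and dispase digestion, followed by 3 h of attachment to plastic. The difference in handling coincides with the difference in cell kind, so the comparison covers both together. Libraries were made with a stranded mRNA kit, per the labels' protocols. Reads were aligned with STAR to the mouse build mm10 (GRCm38), per the submitters' processing notes, which give no version. The counter, its strand setting and the annotation are not given in the sources used here, so antisense and overlapping genes cannot be told apart with certainty.

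The authors deposited 1 table of whole-number read counts, not normalized, with 24454 Entrez gene rows and 8 sample columns, all of which were used. Gene symbols came from a RefSeq table of the same build (GRCm38.p6) for 24375 IDs and from GENCODE for 7. The 72 IDs without a symbol held 0.913% to 2.52% of the counts of a library and stayed in the library sizes and tests. In 4242 rows every count was 0. No gene of the mitochondrial genome was in the table. Total counts per library ran from 10494154 to 11805803. A count of 0 in a library allows up to 3 counts, which equals 0.254 to 0.286 CPM (counts per 1000000). This floor is on the unscaled library total, not on the scaled library size used for the CPM below. Reads carry no molecular identifiers, so floors and counting intervals cover counting error only.

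Genes that share sequence can share reads. Of 14315 rows with at least 100 counts, 77 had the same count as another row in all 8 libraries. The 8 Ugt1a rows, which share exons, correlated at r of at least 0.9995 with each other on log2 counts, across libraries, and values of single Ugt1a genes are therefore uncertain. The same holds for near-identical copies such as Hspa1a and Hspa1b, and for Lyz1 and its paralog Lyz2.

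Tests were run on the counts with edgeR 4.0.16 in R 4.3.3: filterByExpr kept 14707 genes, libraries were scaled by TMM, and the quasi-likelihood test was used with robust estimation and Benjamini-Hochberg adjustment. TMM factors ran from 0.841 to 1.11 in crypts and from 1.05 to 1.10 in myofibroblasts. Calls were made at an adjusted p under 0.05, and a second test asked for more than a 2-fold change (glmTreat). Log2 fold changes are crypts minus myofibroblasts, and the SE is the one implied by the test. CPM are on the TMM-scaled library size and are given as mean ± SD over the 4 samples of a group. A fold against a group with no count is a lower bound taken at 3 counts over the group, and with 1 to 3 counts the ratio is given with its exact (Clopper-Pearson) 95% interval.

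Gene lists for xenobiotic defence, niche signals, cell processes and cell type markers, and the rule for named genes, were fixed before the data were examined. For 45 lists with at least 3 tested members, camera from limma 3.58.1 was run on log2 CPM (prior count 2) with a preset inter-gene correlation of 0.01, adjusted over the lists, and repeated with the correlation estimated. The summed CPM of each of 47 lists was compared by a 2-sided exact permutation test over the 70 assignments of the 8 samples, whose smallest p is 0.0286. The rule names 24 genes whatever their value. It adds the 5 largest and the 5 smallest log2 fold changes among genes past the 2-fold test with a mean of at least 100 CPM in the higher group. It also adds, per list, up to 3 called members with the highest CPM, including at least 1 in each direction. Marker and process lists could be given by counts alone, and the 7 such lists with named genes (cell cycle, immediate early, heat shock, inflammatory, enterocyte, macrophage and lymphocyte) were chosen after values had been seen, which also set which genes were screened for libraries standing apart. Genes outside the rule were named after their values were seen: Erbb3, Krt19, Xist, the receptors, Hox genes, and colon, liver, squamous, stomach and pancreas genes.

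Replicates were compared first. Pearson correlations of log2 CPM ran from 0.9500 to 0.9870 among crypts, from 0.9476 to 0.9907 among myofibroblasts and from 0.4221 to 0.5490 between kinds, and no pair agreed within sampling noise (chi-square per gene of at least 6.35). The fit was tested on simulated counts for this comparison over 14707 genes, of which 200 were changed. It called 46.0% and 58.0% of genes raised and lowered by 1 on the log2 scale, 92.0% and 80.0% at 2 on the log2 scale, and 0.062% of unchanged genes. With only 200 genes changed, the simulation does not show how scaling and error behave when most genes differ, as in the data. Alternatives were RLE, upper quartile and plain library size scaling, other filters, DESeq2 1.42.0, limma voom, the sample number as a block, and each library left out. Added after seeing the data were fits without both libraries numbered 1, without both numbered 4, and with the Ugt1a genes counted once, and 10 further lists of tissue markers, receptors and Hox genes.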

Results

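RNA-seq counts were compared between intestinal crypts, the epithelial pockets that hold the stem cells, and the myofibroblasts that lie beneath them in the mouse small intestine. The series title places the comparison in the question of how the stem cell niche withstands foreign compounds. Each kind had 4 samples, with 10494154 to 11805803 counts per crypt library and 10620144 to 11759841 per myofibroblast library. Counts were detected for 16854 to 17296 genes in crypts and for 18003 to 18232 genes in myofibroblasts. The first principal component of log2 CPM took 92.5% of the variance and separated the kinds.

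The libraries carried the messages that their labels imply, beside those of other cells. Macrophage markers summed to 14249 ± 2422 CPM in myofibroblast libraries, against 1575 ± 144 CPM for myofibroblast and 4712.3 ± 252.5 CPM for fibroblast markers. Of the macrophage sum, Cd74 held 7423.8 CPM and H2-Aa 2879.2 CPM on average. Sums of different lists depend on a few abundant genes and do not measure shares of cells. Enterocyte markers summed to 67237 ± 20664 CPM in crypt libraries, against 1064 ± 463 CPM for stem cell markers. In crypts, 14 of 15 epithelial markers were higher and 1 did not pass, and 12 of 13 fibroblast markers were lower. Epcam, an epithelial adhesion molecule, stood at 2366 ± 479 CPM (SD, n = 4) in crypts and 37.1 ± 45.9 CPM in myofibroblasts. Vil1, a brush border protein, stood at 4074 ± 999 CPM and 12.4 ± 10.7 CPM. Without myofibroblast sample 4 their log2 fold changes were 7.38 and 9.16 instead of 6.00 and 8.36. The stem cell marker Lgr5 (Entrez 14160, chromosome 10, 115450314 to 115587780, GRCm38) was at 19.0 ± 2.68 CPM in crypts and 0.595 ± 0.193 CPM in myofibroblasts, a log2 fold change of 4.98 ± 0.23 (SE). Olfm4, another stem cell marker, and Lyz1, the Paneth cell lysozyme, were also higher in crypts, by 7.27 ± 0.56 and 2.29 ± 0.33 on the log2 scale. Lyz1 shares sequence with the macrophage gene Lyz2, so its level in myofibroblasts is uncertain. In myofibroblasts, Vim was 35.8-fold, the collagen gene Col1a1 11.1-fold, the smooth muscle actin gene Acta2 19.7-fold, Myh11 37.5-fold and Pdgfra 4.63-fold higher.

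Of 14707 genes tested with edgeR, 5983 were higher and 5894 lower in crypts, and 2830 did not pass the threshold. Past the test against 2-fold were 3574 higher and 3664 lower genes. The 4 crypt values and the 4 myofibroblast values did not overlap for 11257 genes, or 76.5%, where chance gives 2.86%. Without both libraries numbered 1, chosen after seeing the data, 5547 genes were higher and 5421 lower, and without both numbered 4 the counts were 5998 and 6083. Among genes past the 2-fold test with a mean of at least 100 CPM in the higher group, Il6, Cxcl1, Ccl7, Has1 and Sele had the 5 smallest fitted log2 fold changes. Il6 and Has1 had no count in any crypt library and 1081 ± 253 and 201 ± 25.2 CPM in myofibroblasts, and were at least 14930-fold and 2774-fold lower. Sele, an endothelial adhesion molecule, also had no count in crypts and was at least 2542-fold lower. Cxcl1, a neutrophil-attracting chemokine, stood at 0.264 ± 0.0701 against 7962 ± 2051 CPM. Ccl7 had 1 count in crypts, in sample 3, and its ratio of myofibroblasts to crypts was 30290 (exact 95% interval 5436 to 1196000). Without that sample no count remained, and the fitted log2 fold change was -16.00 instead of -14.33. The 5 largest, under the same limits, were those of Slc5a12, Apoc3, Lct, 2010106E10Rik and Cyp3a11. Slc5a12, a monocarboxylate transporter, had no count in myofibroblasts and was at least 3444-fold higher in crypts. The apolipoprotein gene Apoc3 had a ratio of crypts to myofibroblasts of 17100 (exact 95% interval 4735 to 141200) and 2010106E10Rik one of 9939 (2751 to 82080), each from 2 myofibroblast counts. Both counts of 2010106E10Rik were in myofibroblast sample 1, without which none remained and the fitted log2 fold change was 15.22 instead of 13.00. Lct, which encodes lactase, was at 3014 ± 1218 against 0.320 ± 0.150 CPM, and the drug-metabolising Cyp3a11 at 637 ± 258 against 0.0847 ± 0.00336 CPM.

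The drug efflux pumps of the ABC family were split between the kinds. Of 11 tested members, 6 were higher and 5 lower in crypts, and camera gave an adjusted p of 0.584 for the list (adjusted p = 0.802 with an estimated correlation). Crypts carried Abcb1a, a P-glycoprotein gene, at 431 ± 43.7 CPM against 89.8 ± 21.2 CPM in myofibroblasts (log2 fold change 2.26 ± 0.18, edgeR adjusted p = 2.45e-06). The neighbouring paralog Abcb1b went the other way, at 32.1 ± 2.26 against 88.7 ± 14.0 CPM (-1.47 ± 0.13, edgeR adjusted p = 4.6e-06). Abcb1a lies on chromosome 5 at 8567091 to 8748575 and Abcb1b at 8798147 to 8866314 (GRCm38). Abcc2, an apical conjugate pump, was at 365 ± 106 against 2.05 ± 0.932 CPM (7.48 ± 0.38), and Abcg2, the breast cancer resistance protein gene, at 221 ± 46.7 against 9.65 ± 0.865 CPM (4.52 ± 0.19). Abcc1, another conjugate pump, was higher in myofibroblasts, at 395 ± 96.4 against 10.1 ± 2.73 CPM (-5.28 ± 0.27, edgeR adjusted p = 1.5e-07). Abcc4 was also higher in myofibroblasts (-1.67 ± 0.30), and Abcc3 was higher in crypts (1.27 ± 0.22, edgeR adjusted p = 0.000481) without passing the 2-fold test (adjusted p = 0.0821). The summed CPM of the list was 1282 ± 158 in crypts and 704 ± 111 in myofibroblasts (exact permutation p = 0.0286, the smallest possible, adjusted 0.0353). Over all ABC genes, 20 of 39 were higher and 14 lower (camera adjusted p = 0.225; adjusted p = 0.695 with an estimated correlation), with the sterol pump gene Abcg5 higher by 9.86 ± 0.45.

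**Figure D1:**
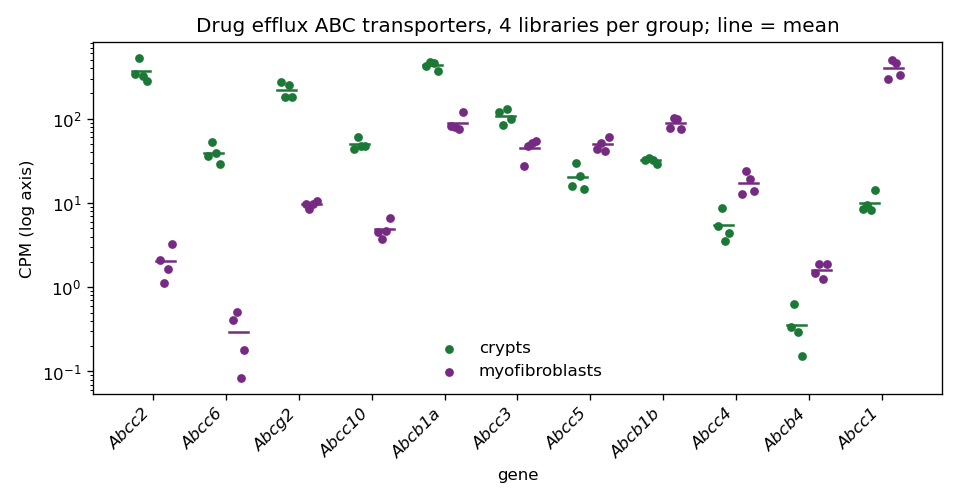
CPM on a log axis of the 11 tested drug efflux ABC genes, ordered by fold change, with 1 point per library (4 crypts, 4 myofibroblasts) and a line at each group mean. Abcc2, Abcg2 and Abcb1a sit higher in crypts, and Abcc1, Abcb1b and Abcc4 higher in myofibroblasts.

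Enzymes that modify and conjugate foreign compounds were mostly higher in crypts. Of 35 tested Cyp genes of families 1 to 4, 30 were higher and 2 lower, with a median log2 fold change of 5.79 (camera adjusted p = 9.55e-08; adjusted p = 0.527 with an estimated correlation). Cyp4f14 was higher by 10.29 ± 0.93 and Cyp4v3 by 4.88 ± 0.31, while Cyp1b1, which metabolises oestrogens and aromatic hydrocarbons, was lower, at -3.73 ± 0.34. Among 37 other phase 1 enzymes, 25 were higher and 8 lower (camera adjusted p = 0.00308; adjusted p = 0.547 with an estimated correlation). The carboxylesterase gene Ces2e and the xanthine oxidase gene Xdh were higher by 9.20 ± 0.82 and 2.05 ± 0.23, and Por, the electron donor of microsomal P450 enzymes, was lower, at -1.26 ± 0.23. Of 48 phase 2 genes, 43 were higher and 2 lower (camera adjusted p = 5.35e-09; adjusted p = 0.527 with an estimated correlation). With the Ugt1a genes counted once, 36 of 41 were higher, and the summed CPM was 4885 ± 1084 in crypts and 639 ± 65.9 in myofibroblasts (exact permutation p = 0.0286) instead of 7517 ± 1625 and 819 ± 107. Ugt2b34 and Ugt1a7c, glucuronosyltransferase genes, were higher by 8.02 ± 1.02 and 3.73 ± 0.23, the second with uncertain assignment of reads. Without myofibroblast sample 4, Cyp4f14, Ces2e and Ugt2b34 were higher by 12.21, 10.28 and 9.98. The glutathione transferase gene Gsta3 was lower, at -2.31 ± 0.34. Beside these enzyme groups, enterocyte markers summed to 67237 ± 20664 CPM in crypts and 247 ± 71.3 in myofibroblasts, against 1064 ± 463 and 356 ± 6.16 CPM for stem cell markers. Crypt sample 4 had the lowest enterocyte sum, 36504 CPM, and the lowest sums of Cyp genes, 3950 CPM against 6758 to 8067 in the other crypt samples, and of phase 2 genes, 6103 CPM against 6948 to 9856.

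Uptake carriers and xenobiotic sensors were divided. Of 28 uptake carriers, 17 were higher and 5 lower (camera adjusted p = 0.0184; adjusted p = 0.527 with an estimated correlation). The peptide transporter gene Slc15a1 was higher by 11.76 ± 0.56 (12.59 without myofibroblast sample 4) and the nucleoside transporter gene Slc28a2 by 3.76 ± 0.57, and the organic anion transporter gene Slco3a1 was lower, at -3.68 ± 0.11. Of 15 sensors, 10 were higher and 4 lower. The camera test gave an adjusted p of 0.049, which rose to 0.0511 with plain library sizes, to 0.0544 with the replicate block, to 0.0553 without myofibroblast sample 1, to 0.0502 without myofibroblast sample 3 and to 0.0541 without both libraries numbered 1 (adjusted p = 0.547 with an estimated correlation). Nr1i2, the pregnane X receptor gene, was at 124 ± 10.2 CPM in crypts and 0.427 ± 0.201 CPM in myofibroblasts (8.16 ± 0.23), Vdr was higher by 4.79 ± 0.17 and Hnf4a by 6.74 ± 0.74 (7.79 without myofibroblast sample 4). Ahr, the aryl hydrocarbon receptor gene, was higher in myofibroblasts, at 48.2 ± 8.55 against 19.8 ± 1.75 CPM (-1.28 ± 0.15), as was Nfe2l2 (-0.49 ± 0.13). Among 24 antioxidant genes, 7 were higher and 12 lower in crypts (camera adjusted p = 0.323; adjusted p = 0.821 with an estimated correlation). Hmox1, which encodes haem oxygenase, was at 3.50 ± 2.04 CPM in crypts and 5458 ± 2796 CPM in myofibroblasts. It stood at 2829.7 and 3257.7 CPM in myofibroblast samples 1 and 4, and at 8040.5 and 7703.2 CPM in samples 2 and 3. Prdx1 was lower, at -1.49 ± 0.20, and Txn1 higher, by 1.31 ± 0.15.

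DNA repair and apoptosis genes differed by less. Of 41 repair genes, 21 were higher and 6 lower, with a median log2 fold change of 0.39 (camera adjusted p = 0.128; adjusted p = 0.802 with an estimated correlation). That camera adjusted p was 0.0412 without crypt sample 2 and 0.0382 with no filter on low counts. Apex1 and Ercc6 were lower, at -1.43 ± 0.27 and -1.06 ± 0.19. Ercc3 was higher by 0.32 ± 0.10, a call that ended with plain library sizes (edgeR adjusted p = 0.32), with upper quartile scaling (edgeR adjusted p = 0.0652) and without both libraries numbered 1 (edgeR adjusted p = 0.0878). Of 25 apoptosis and p53 genes, 11 were higher and 8 lower (camera adjusted p = 0.657; adjusted p = 0.926 with an estimated correlation). The survival gene Mcl1 was lower, at -1.06 ± 0.18. The cell cycle inhibitor gene Cdkn1a was also lower, with 268 ± 85.1 CPM in crypts and 538 ± 53.7 CPM in myofibroblasts.

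Secreted niche factors of the stromal list were mostly higher in the myofibroblast libraries, where counts cannot tell myofibroblasts from other cells of the preparation. Of 29 stromal niche factors, 25 were lower and 2 higher in crypts, with a median log2 fold change of -3.20 (camera adjusted p = 1.23e-05; adjusted p = 0.527 with an estimated correlation). Rspo3, a Wnt enhancer, was at 95.4 ± 19.5 CPM in myofibroblasts and 0.487 ± 0.148 CPM in crypts (-7.59 ± 0.25). Grem1, a BMP antagonist, was at 90.2 ± 9.15 against 0.112 ± 0.142 CPM (-9.42 ± 0.36, or -10.23 without crypt sample 3). Fstl1 and Cxcl12 were lower in crypts, at -5.55 ± 0.36 and -6.09 ± 0.41, and Bmp3 was higher by 3.94 ± 0.43. Of 9 tested Wnt ligands, 4 were higher and 3 lower (camera adjusted p = 0.988; adjusted p = 0.999 with an estimated correlation). Wnt3, a Paneth cell Wnt, was at 2.75 ± 0.232 CPM in crypts and had 3 counts in myofibroblasts, a ratio of 43.7 (exact 95% interval 14.6 to 215). Wnt4 was higher in crypts by 2.21 ± 0.45, and Wnt11 and Wnt2b were lower, at -7.35 ± 0.41 (-7.94 without crypt sample 1) and -2.30 ± 0.36. Epithelial niche signals went both ways, with 4 of 10 higher and 4 lower (camera adjusted p = 0.972; adjusted p = 0.995 with an estimated correlation). The hedgehog ligand gene Ihh was higher by 6.24 ± 0.30, and the Notch ligand gene Jag1 was lower, at -3.11 ± 0.23. Ereg, an EGF receptor ligand, reached 2054 ± 678 CPM in myofibroblasts and 10.2 ± 1.20 CPM in crypts. Of 13 Wnt response genes, 5 were higher and 6 lower (camera adjusted p = 0.969; adjusted p = 0.998 with an estimated correlation). Axin2 was higher by 3.68 ± 0.15, and Cd44 and Myc were lower, at -5.62 ± 0.25 and -3.54 ± 0.28.

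Cell cycle genes were mostly higher in crypts, with 29 of 36 higher and 2 lower (camera adjusted p = 0.00722; adjusted p = 0.758 with an estimated correlation). Their summed CPM was 1132 ± 542 in crypts, with 1891 in crypt sample 4, and 571 ± 76.1 in myofibroblasts (exact permutation, adjusted p = 0.0689). Mki67 was at 143 ± 88.0 CPM in crypts and 50.9 ± 10.2 CPM in myofibroblasts, Top2a was higher by 2.37 ± 0.42, and Pcna was lower, at -0.86 ± 0.15. Stress and inflammatory messages were abundant in myofibroblasts, whose preparation included digestion and 3 h of attachment. All 21 tested inflammatory genes were lower in crypts, and their summed CPM was 302 ± 20.4 in crypts and 37535 ± 8505 in myofibroblasts (camera adjusted p = 2.85e-10; adjusted p = 0.245 with an estimated correlation). Ptgs2, the inducible cyclooxygenase gene, was at 4.82 ± 2.65 against 5354 ± 1749 CPM, and Cxcl2 at 0.320 ± 0.0691 against 5048 ± 1635 CPM. Of 23 immediate early genes, 21 were lower in crypts and 2 higher (camera adjusted p = 4.94e-06; adjusted p = 0.538 with an estimated correlation). Egr1 and Zfp36 were lower, at -7.04 ± 0.37 and -2.11 ± 0.28, and Klf4, also an epithelial differentiation factor, was higher by 1.89 ± 0.22. Of 13 heat shock genes, 11 were lower (camera adjusted p = 0.000566; adjusted p = 0.527 with an estimated correlation). Hspa1a and Hspa1b, near-identical copies, reached 7008 ± 1120 and 3835 ± 636 CPM in myofibroblasts and 10.3 ± 2.76 and 8.25 ± 1.90 CPM in crypts. Hsp90ab1 was lower, at -1.23 ± 0.26. Interferon response genes were lower in crypts for 18 of 19 members and extracellular matrix genes for 28 of 32 (camera adjusted p = 0.000162 and 9.55e-08; adjusted p = 0.564 and 0.538 with an estimated correlation). All 78 tested oxidative phosphorylation genes were higher in crypts, with a median of 2.16 (camera adjusted p = 3.58e-17; adjusted p = 0.529 with an estimated correlation). Of 24 histone genes, 17 were higher (camera adjusted p = 0.00108; adjusted p = 0.547 with an estimated correlation). Of 82 ribosomal protein genes, 32 were lower and 2 higher, and camera gave 0.00644, or 0.0609 without crypt sample 2 (adjusted p = 0.817 with an estimated correlation). Of 14 housekeeping genes, 4 were higher and 2 lower (camera adjusted p = 0.999; adjusted p = 0.999 with an estimated correlation).

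**Figure D2:**
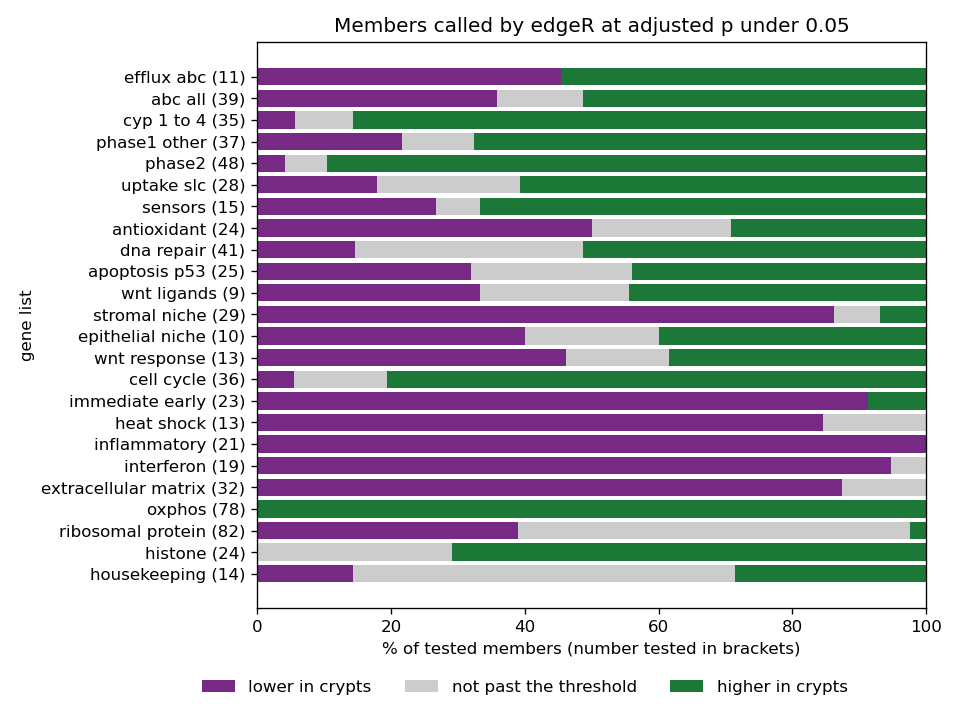
Share of the tested members of each xenobiotic, niche and process list that edgeR called lower in crypts, did not call, or called higher in crypts, in percent, with the number of tested members in brackets. All 78 oxidative phosphorylation genes were higher and all 21 inflammatory genes lower in crypts.

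Markers of the specialised epithelial cells were mostly higher in crypts, with 17 of 17 for enterocytes, 10 of 10 for goblet cells, 12 of 13 for enteroendocrine cells and 11 of 12 for Paneth cells (camera adjusted p = 9.55e-08, 0.000566, 0.002 and 0.00644; adjusted p = 0.527, 0.538, 0.527 and 0.618 with an estimated correlation). Apoa4, a lipid carrier of villus enterocytes, was at 15146 ± 7205 CPM in crypts and 4.15 ± 2.11 CPM in myofibroblasts, and Apoa1 and Anpep were higher by 11.93 ± 0.71 and 5.31 ± 0.36. The epithelial list had a camera adjusted p of 0.00018 (adjusted p = 0.547 with an estimated correlation). Of 15 stem cell markers, 10 were higher and 4 lower, which camera did not call (adjusted p = 0.0732; adjusted p = 0.629 with an estimated correlation) except without crypt sample 2 (adjusted p = 0.0478) and with no filter on low counts (adjusted p = 0.0272). Tuft cell markers were split, with 3 of 7 higher and 2 lower (camera adjusted p = 0.657; adjusted p = 0.849 with an estimated correlation).

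Stromal markers were mostly lower in crypts: 10 of 15 for myofibroblasts, 9 of 10 for smooth muscle, 6 of 7 for pericytes, 5 of 5 for interstitial cells of Cajal and 11 of 12 for endothelium. Their camera adjusted p were 0.0299, 0.000581, 0.0127, 0.0203 and 0.0036, and 0.000139 for fibroblasts (adjusted p = 0.694, 0.538, 0.547, 0.527, 0.547 and 0.527 with an estimated correlation). The myofibroblast list had 0.0573 without crypt sample 4. Immune markers marked both preparations. Ptprc, carried by all leukocytes, was at 84.3 ± 32.3 CPM in crypts and 192 ± 32.3 CPM in myofibroblasts. Of 15 macrophage markers, 14 were lower in crypts and Cx3cr1 was higher (camera adjusted p = 0.00235; adjusted p = 0.595 with an estimated correlation), with the antigen presentation genes Cd74 and H2-Aa at -1.79 ± 0.31 and -1.99 ± 0.29. Of 11 lymphocyte markers, 9 were higher in crypts and 2 lower (camera adjusted p = 0.0217; adjusted p = 0.595 with an estimated correlation). Gzma and Gzmb, genes of cytotoxic granules, were higher by 4.84 ± 0.50 and 4.21 ± 0.36, and Cd4 was lower, at -2.38 ± 0.40. All 8 B and plasma cell markers were lower in crypts (camera adjusted p = 0.00462; adjusted p = 0.527 with an estimated correlation).

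Of the remaining marker lists, all 5 erythrocyte genes were higher in crypts (camera adjusted p = 0.0203; adjusted p = 0.547 with an estimated correlation). Glia and neuron markers were lower for 7 of 8, granulocyte and mast cell markers for 3 of 5 and mesothelium markers for 5 of 7, and camera called none of these lists (adjusted p = 0.0511, 0.657 and 0.288; adjusted p = 0.547, 0.849 and 0.758 with an estimated correlation). The glia and neuron list passed without crypt sample 1, 2 or 3 (adjusted p = 0.0425, 0.0486 and 0.0457) or myofibroblast sample 3 (0.0483), and without both libraries numbered 1 (0.0392). Of 2 tested adipocyte genes, 1 was higher and 1 lower. Xist was expressed in all libraries, at 472 ± 175 CPM in crypts and 735 ± 138 CPM in myofibroblasts. Of the 11 pancreatic acinar genes, 0 passed the edgeR test, with 0 at an unadjusted p under 0.05 by edgeR, DESeq2 or voom (camera adjusted p = 0.83; adjusted p = 0.995 with an estimated correlation), and their sum ran from 38.4 to 11894 CPM among crypts and from 8.52 to 13074 CPM among myofibroblasts.

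**Figure D3:**
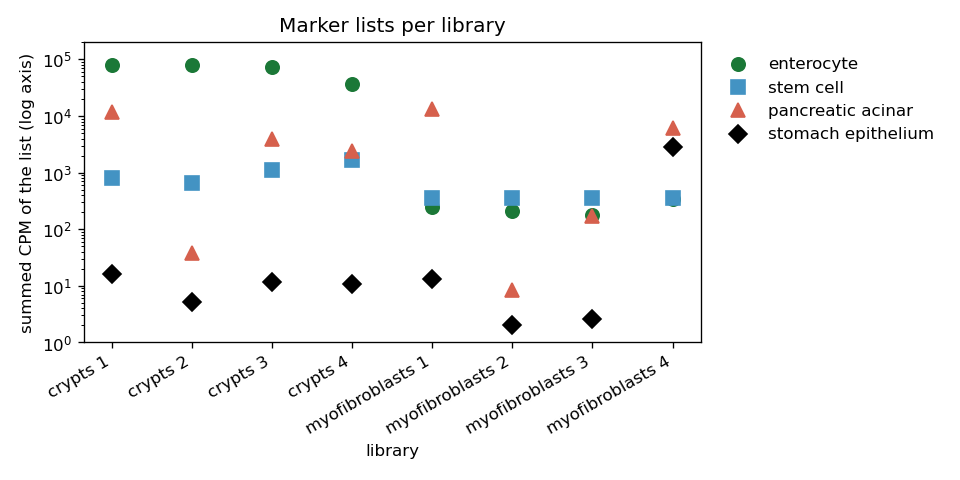
Summed CPM on a log axis of the enterocyte, stem cell, pancreatic acinar and stomach epithelium lists in each of the 8 libraries. Acinar sums run from 8.52 to 13074 CPM across libraries of both kinds, and the stomach list reaches 2837 CPM in myofibroblast sample 4 alone.

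Over the 45 lists, camera called 15 higher and 15 lower in crypts. With an estimated correlation it called 0, with 1 list at an unadjusted p under 0.05 and no other tool run for that test. Summed CPM differed for 38 of 47 lists by the exact permutation test after adjustment. The 9 that did not pass were DNA repair, apoptosis, Wnt ligands, cell cycle, ribosomal proteins, housekeeping, sex-linked, tuft cell and pancreatic acinar genes. Adjusted over the list alone, the member counts were the same for 43 lists. They were 44 higher for phase 2, 20 higher for DNA repair, 11 lower for ribosomal proteins and 3 higher for housekeeping genes. Sums and member directions parted where 1 abundant gene dominated: the epithelial niche sum was 9.22-fold lower in crypts with a median log2 fold change of 0.16, through Ereg. The glia and neuron sum was 6.61-fold higher, through Erbb3, with a median of -3.47, and the mesothelium sum, through Krt19, was 954 ± 275 CPM in crypts and 79.2 ± 90.3 CPM in myofibroblasts with 5 of 7 members lower. Without myofibroblast sample 4 the log2 ratio of the mesothelium sums was 4.79 instead of 3.59, and the log2 fold changes of Erbb3 and Krt19 were 7.33 and 5.97 instead of 6.24 and 4.10. The apoptosis and tuft cell sums were 1.05-fold and 1.30-fold lower in crypts with medians of 0.38 and 0.28. The median, the mean and the camera direction also differed in sign for Wnt ligands (median 0.01, mean -0.15), Wnt response genes (-0.32 and 0.43), housekeeping genes (-0.08 and 0.17) and pancreatic acinar genes (-0.18 and -0.13, camera higher). No list median moved when genes without a count in a group were set to their bound.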

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

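All tests of explanations in this part were chosen after the result was seen. Among 270 sets of 4 values, 1 library stood apart from the other 3 of its group in 23, where chance gives about 1 in 20, or 13.5. Of these, 9 were in myofibroblast sample 4 and 7 in crypt sample 4. The 23 include Wnt3 and 2010106E10Rik in myofibroblasts, with 3 and 2 counts over the group, and Ccl7 in crypts, with 1. So few counts do not show that a library stands apart. This screen cannot show samples that part in pairs. Interferon response genes summed to 12161 and 11960 CPM in myofibroblast samples 1 and 4, and to 5255.6 and 3944.1 CPM in samples 2 and 3. Inflammatory genes parted the other way, with 31462 and 29564 CPM against 47555 and 41559 CPM. Chi-square per gene was 23.47 between samples 1 and 4, 6.346 between 2 and 3, and 54 to 55.34 across these pairs. By Pearson correlation, however, sample 1 was closer to sample 3 (0.9784) than to sample 4 (0.9734). The cause of this pairing was not tested.

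In myofibroblast sample 4 the epithelial markers summed to 1593 CPM against 69.8 to 241 in the other 3, the mesothelium list, through Krt19, to 213 against 18.5 to 49.8, and the enteroendocrine list to 75.3 against 31.9 to 37.5. Epcam was at 105 CPM against 8.60 to 21.9, Ugt2b34 at 9.63 against 0.256 to 1.22, Cyp4f14 at 3.21 against 0.244 to 0.256 and Slc15a1 at 0.624 against 0.0829 to 0.1703. Abcb1a was at 121 CPM against 76.3 to 82.2, and Wnt4 at 5.97 against 3.24 to 3.34. In the other myofibroblast samples, Wnt3 had no count (0 CPM) in sample 2 against 0.0814 to 0.0891 CPM, Cx3cr1 was at 1.08 CPM in sample 3 against 0.767 to 0.814, and 2010106E10Rik at 0.163 CPM in sample 1 against 0 in the rest.

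In crypt sample 4 the enterocyte list summed to 36504 CPM against 73721 to 79849 in the other 3, Wnt response genes to 403 against 261 to 279, and the sex-linked list, almost all Xist, to 733 against 369 to 416. Axin2 was at 106 CPM against 77.9 to 82.6, Cyp4v3 at 498 against 998 to 1100, 2010106E10Rik at 230 against 489 to 538 and Hspa1b at 5.42 against 8.98 to 9.53. In crypt sample 3, Ugt1a7c was at 623 CPM against 411 to 417, Gsta3 at 5.33 against 1.91 to 2.33 and Ccl7 at 0.0987 against 0. Acta2 was at 28.7 CPM in crypt sample 2 against 11.2 to 13.7.

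Stomach epithelial messages were concentrated in myofibroblast sample 4, where a list of 12 such genes, written after the epithelial markers had stood out but before its own genes were looked at, summed to 2837 CPM against at most 16.3 in any other library. Muc6, Tff2, Gkn3, Gkn2, Tff1 and Gkn1 were at 924, 832, 368, 224, 188 and 182 CPM there. Epithelium of the kind in the crypt libraries is argued against as the source, since the crypt library with the most held only 0.576% of that sum. Small intestinal epithelium that EDTA does not release was not measured, so this comparison cannot speak to it. A candidate explanation is stomach tissue in the pool, for which 66.7% of the list, or 8 of 12 genes, was at least 10 times above every other library, although the parietal cell genes Atp4a and Atp4b were at 0.0891 and 0 CPM. No biological explanation was tested, because the groups give none for 1 sample.

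Pancreatic acinar messages appeared in both kinds of library, with summed CPM of 11894, 38.4, 3905 and 2461 in crypt samples 1 to 4 and of 13074, 8.52, 173 and 6056 in myofibroblast samples 1 to 4. A difference between the kinds is argued against only as the main source of this spread, since it took 2.99% of the variance of the log2 sum. With so wide a spread within each kind, a smaller difference between them cannot be excluded. Crypt reads assigned to myofibroblast samples 1 and 4 are argued against, since enterocyte genes reached at most 0.848% of the summed level needed. For sample 3 that share was 15.4%, with 85.2% of the enterocyte sum from Anpep, and a test per gene, chosen after this share was seen, argues against crypt reads there too, with 14 of 17 enterocyte genes under 10% of their needed level and Anpep alone over 50%. Pancreas tissue carried along during dissection may account for the pattern: over the 6 libraries with over 100 CPM, 9 further acinar genes, those over 1 CPM in each, kept a median SD of 0.48 for log2 of their ratio to Amy2a5, against 2.34 for Amy2a5 itself. Over all 16 further genes with a count in each of these libraries the median was 0.53, with 11 under 1, among them the near-identical Amy2b, and the other 5, Zg16, Spink1, Bhlha15, Reg1 and Rnase1, did not keep 1 ratio.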

How the results depend on the processing

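Fits without both libraries numbered 1 or 4, and with Ugt1a counted once, were chosen after seeing the data. The 4 counts of called genes stayed within 1.5 times their values under every alternative run, and of the 90 genes that the rule names 1, Ercc3, lost its call. Of 17 called genes outside the rule that were run under the alternatives, Muc6 and Xist lost theirs under several alternatives. Plain library size moved the median log2 fold change of all genes from 0.01 to -0.17, upper quartile scaling to -0.10 and no filter to -0.18. With 1 library left out, genes higher in crypts ranged from 5821 to 6070, genes lower from 5666 to 6139, genes over 2-fold higher from 3485 to 3642 and lower from 3574 to 3928, camera lists from 29 to 32 of 45, and summed lists from 30 to 38 of 47.

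An estimated correlation left 0 of the 30 camera calls. Whether the sample numbers pair the samples stays open: deviations of same-numbered samples correlated at 0.27, 0.24, -0.16 and -0.11. Samples 1 and 2 correlated best with their own number, and samples 3 and 4 with another number. With the replicate block, 5707 genes were higher, 5662 lower, 3451 over 2-fold higher and 3583 over 2-fold lower, and 29 lists were called, without the sensors. The blocked sums gave 0 calls, because sign flips of 4 differences cannot go below an exact p of 0.125.

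The gene Muc6, at -7.03 on the log2 scale with all libraries, turned to 1.18 without myofibroblast sample 4 and 1.34 without both libraries numbered 4, within -7.47 to 1.18 over the libraries left out. No other called gene was called in the opposite direction under any alternative run. Among lists and sums, the directions that turned were of lists without a call, and the cause was not tested. For Wnt ligands the camera adjusted p was then 0.965 with plain library size, 0.998 and 0.81 without crypt sample 3 or 4, 0.992 without myofibroblast sample 4 and 0.751 without both libraries numbered 4. For Wnt response genes it was 0.965 with plain library size and 0.935 with no filter. For housekeeping genes it was 0.976 with RLE, 0.887 with plain library size, 0.999 without crypt sample 3, and 0.996, 0.986 and 0.992 without myofibroblast sample 1, 3 or 4, within a range of 0.867 to 0.999 over the libraries left out. For acinar genes it was 0.794 without myofibroblast sample 2, within 0.395 to 0.989. The log2 ratio of sums turned to -0.0085 for DNA repair with plain library size and to 0.0358 for apoptosis genes without crypt sample 4. For acinar sums it turned to 0.33 and 0.13 without crypt sample 2 or 4, and to 1.14 and 0.05 without myofibroblast sample 1 or 4, within -1.18 to 1.14.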

Other observations

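Receptors and Hox genes, on lists written after the data had been seen, also differed between the kinds. Of 44 tested receptors of secreted niche factors, 9 were higher and 29 lower in crypts by edgeR, with a median log2 fold change of -1.39. Crypts carried more Lgr4, an R-spondin receptor gene, at 124 ± 30.9 CPM against 8.997 ± 1.19 (SD, n = 4), more Fzd5, at 150 ± 35.3 against 22.4 ± 2.33, and more Erbb2 and Erbb3, at 216 ± 23.8 and 362 ± 59.6 against 10.8 ± 1.56 and 4.82 ± 5.18. Myofibroblasts carried more Fgfr1, at 783 ± 94.6 against 5.93 ± 2.93 CPM, more of the chemokine receptor gene Cxcr4, at 134 ± 7.17 against 2.15 ± 0.987, and more Egfr, at 126 ± 15.9 against 34.2 ± 4.53. They also carried more Il6st and Osmr, which encode receptors of the interleukin 6 family, at 326 ± 39.97 and 134 ± 5.66 against 40.04 ± 12.3 and 4.16 ± 2.12. These genes were chosen after their values were seen, and without myofibroblast sample 4 the log2 fold change of Erbb3 was 7.33 instead of 6.24. Of 17 tested Hox genes, 13 were lower in crypts and Hoxb9 was higher, by 3.78 on the log2 scale.

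The other added lists hold genes of neighbouring tissues. Colon epithelium genes were higher in crypts for 7 of 8, with 144 CPM in myofibroblast sample 4 against at most 3.42 in the other myofibroblast samples. Of this, 87.5 CPM was Car1, which had no count in the other 7 libraries. Hepatocyte genes summed to 776 ± 385 CPM in crypts and 152 ± 16.6 in myofibroblasts, with 5 of 6 higher in crypts. Of these, Cps1 made up 713 CPM in crypts and Trf 146 CPM in myofibroblasts, and Alb was at 0.262 CPM in crypts and 0.0446 CPM in myofibroblasts. Duct genes summed to 768 ± 50.9 and 164 ± 79.7 CPM, with 4 of 9 higher and 3 lower. Squamous genes stood at 100 CPM in myofibroblast sample 4, of which 91.1 CPM was Sprr1a alone, and at most 15.9 elsewhere, with 1 of 2 lower in crypts. Islet genes summed to at most 8.79 CPM and reproductive tract genes to at most 19.7 CPM in any library, with 1 of 1 and 1 of 2 tested genes higher in crypts. The 18 further acinar genes summed to 6161 ± 1928 CPM in crypts, most of it the goblet cell gene Zg16, and 501 ± 626 in myofibroblasts, with 2 of 16 called, Zg16 and Spink1, both higher in crypts, by 7.83 and 8.06 on the log2 scale and by 8.78 and 9.05 without myofibroblast sample 1. Of 4 tested stomach genes, 1 was called, Muc6, lower in crypts (edgeR adjusted p = 0.0335), and without myofibroblast sample 4 its direction turned, to 1.18 on the log2 scale (edgeR adjusted p = 0.0113). Its call also ended without crypt sample 1, 2, 3 or 4 (edgeR adjusted p = 0.0698, 0.0987, 0.0729 and 0.104).

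The inflammatory, immediate early and heat shock messages of the myofibroblast libraries were weighed against explanations chosen after the result was seen. For the inflammatory list a larger share of resident macrophages alone is argued against: its median log2 fold change lay -6.61 from that of the macrophage markers, with quartiles of -13.68 to -5.44 against -2.91 to -1.73. For the immediate early and heat shock lists more macrophages stay open, with medians -1.58 and 0.0376 from that of the markers and quartiles of -6.24 to -1.55 and -3.24 to -0.64 that overlap theirs. Induction during digestion or the 3 h on plastic may account for all 3 lists, and 21 of 23 immediate early genes were lower in crypts, but handling and cell kind coincide, so this cannot be told apart from a difference between the cells. A difference between the cells themselves stays open and untested.

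The splits of the samples were fixed before their results were seen. Of the 35 splits of the 8 samples into 4 and 4, 1, the real one, gave 11877 called genes and 7238 genes over 2-fold. The highest other split gave 0 by edgeR in both. At an unadjusted p under 0.05 by edgeR the others gave 3 to 845 genes against 12031, and no other tool was run on the splits. Every other split mixed the kinds within its groups, and 1 of 35 is the smallest share possible. Chance is therefore argued against for these counts only at that level. For the number of lists called by camera with a preset correlation, 4 of the 35 splits gave at least the real 30, and the highest other gave 31, so chance cannot be excluded for that number by this test. The other 3 kept 3 of 4 samples of each kind together and so carried part of the difference between the kinds, and the 18 splits that mixed the kinds evenly gave at most 20 lists.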
